A study of Mus musculus with 6 samples.

How the data were processed

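Total RNA of flow-sorted peripheral blood neutrophils from control mice and from mice given AVP for 30 days was extracted with a phenol-based reagent, made into TruSeq libraries and sequenced as paired reads on a NovaSeq instrument, per the labels' protocols. Each group had 3 samples, assigned from the labels. Per the submitters' processing notes, bcl2fastq 2.19, cutadapt 1.16.5, HISAT2 2.1, featureCounts 1.6.4 and DESeq2 2.11.40.6 were used by the authors, with the mm10 build; the role of each and the annotation release are not given in the sources used here. The deposited values are taken here to be FPKM per gene: the files do not name their unit, and this was inferred from the values, which are not whole numbers, differ in total between libraries and, multiplied by transcript length, sum to 733495 to 778382 per library, below the scaling constant of FPKM. Library totals were 755140 to 829725 FPKM. Because the values are not counts, the count-based test fixed before the data were examined could not be used, and limma took its place. No total count exists for such values, so the depth (about 14327000 to 16935000 fragments) is an estimate from the step size of low values in short pseudogenes. An exact 0 in such values can be a failed estimate, so genes are said to be listed at 0. Levels of genes with near-identical copies are uncertain.

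Of 47561 features, 44705 (94%) were matched by name to a RefSeq table of the GRCm38 assembly, from which identifiers and coordinates were taken. Genes with at least 1 FPKM in at least 3 libraries were kept (8523). Libraries were scaled by a trimmed mean of log ratios to the geometric mean library (30% of ratios and 5% of levels trimmed at each end, without weights). Values were analysed as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. Group differences were tested with limma 3.58.1 in R 4.3.3, with variances moderated along an intensity trend, Benjamini-Hochberg adjustment and a threshold of 0.05, without a term for the replicate number. Printed FPKM are the deposited values before scaling.

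There were 38 gene lists fixed before the data were examined, for neutrophil biology, the ligand family in the title, stress and metabolism, and other blood cells; 832 of their 834 members were found. Lists with at least 3 tested members (35) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. With an estimated correlation, camera also takes the residual degrees of freedom, 4 with all 6 libraries and 3 with a library left out. A call can then be lost even where members do not vary together. Members were also adjusted over the list alone. The genes named were chosen by a rule fixed before the data were examined. It takes up to 12 genes each way past the threshold (there were 0), and the 15 genes with the smallest p among those with a mean of at least 5 FPKM and groups that do not overlap, leaving out predicted genes, pseudogenes and antigen receptor segments. It adds the IL-36 genes and Il1rl2, and from each list up to 4 members that pass or else the 2 with the highest mean. The rule's adjusted p was read as adjusted over the list alone, and members of tested lists with no call of either kind are not named under it, while the 3 lists that were too short to test (Avp peptide, T cell and basophil) are.

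The procedure was tested on simulated data for the comparison of AVP with control, on 8523 genes. At a threshold of 0.05 it recovered 7 of 68 genes changed by 1 on the log2 scale, 24 of 66 changed by 2 and 55 of 66 changed by 4. There were 3 false calls, and 0 of 37 unchanged lists were called. The changed genes were drawn only from those with a mean level above about 20 FPKM, so recovery among lower genes was not measured. Noise was simulated independently for each gene, so the 0 of 37 does not bear on lists whose members vary together. The alternatives were other scalings, no filter and a stricter filter, a replicate block, leaving out each library, robust moderation, removal of haemoglobin, immunoglobulin and mitochondrial genes, stricter thresholds, other pseudocounts (0.1 and 5) and no intensity trend. Exact permutation tests, tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.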

Results

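The transcriptomes of neutrophils sorted by flow cytometry from mouse peripheral blood were measured by RNA sequencing, in 3 control samples and in 3 samples from mice given AVP for 30 days. The labels do not expand the abbreviation AVP. Each library listed 47561 gene and transcript features in FPKM, fragments per kilobase of transcript scaled to sequencing depth, of which 10628 to 12195 lay above 0 and 7688 to 8842 reached 1 FPKM. The sequencing depth, estimated from the value a fragment contributes to short pseudogenes, was about 14327000 to 16935000 fragments per library. The calprotectin genes S100a8 and S100a9, the most abundant neutrophil transcripts, took 18.4% to 23.9% of the total FPKM. Nothing in the labels says that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

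The series title names IL36G, a cytokine of the interleukin-1 family, and the comparison of AVP with control asks whether its gene and others differ in blood neutrophils after AVP. Il36g, listed under its older symbol Il1f9, stood at 266 ± 29.4 FPKM (SD, n = 3) after AVP and at 102 ± 29.2 FPKM (SD, n = 3) in controls, and all 3 AVP libraries lay above all 3 control libraries. The gene is protein-coding (gene identifier 215257) and lies on chromosome 2 from 24186476 to 24193567 in GRCm38, the assembly of the mm10 build. Its fitted log2 fold change was 1.495 (SE 0.29), with an adjusted p of 0.159 over all genes tested. Adjusted over the list alone, Il36g rose, with an adjusted p of 0.00365 by limma among the 9 tested members of the IL-36 and IL-1 family. The list was fixed because the series title names this gene, and the title may rest on these same samples. Neither this test nor others of the list are therefore independent support for a rise of Il36g. Il1b, the inflammatory cytokine interleukin-1 beta, rose by the same test, from 2285 ± 151 to 3794 ± 280 FPKM (SD, n = 3), a log2 fold change of 0.81 (SE 0.17). Il1r2, the decoy receptor that binds interleukin-1 without signalling, rose from 87.8 ± 19.4 to 304 ± 94.9 FPKM (SD, n = 3), a log2 fold change of 1.83 (SE 0.35).

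The other IL-36 genes, Il1f6 (Il36a), Il1f8 (Il36b) and Il1f5 (Il36rn), and the receptor gene Il1rl2 were listed at 0 in all 6 libraries. Of the 9 tested members of the family, 3 rose and 6 did not pass, adjusted over the list alone, and 0 passed over all genes. The family rose as a list in limma's camera test with a preset correlation of 0.01 (adjusted p = 0.000484), with an adjusted p = 0.255 with an estimated correlation. For Il36g on its own, the exact permutation test, two-sided, gave p = 0.1, the smallest that 3 libraries against 3 allow.

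**Figure D1:**
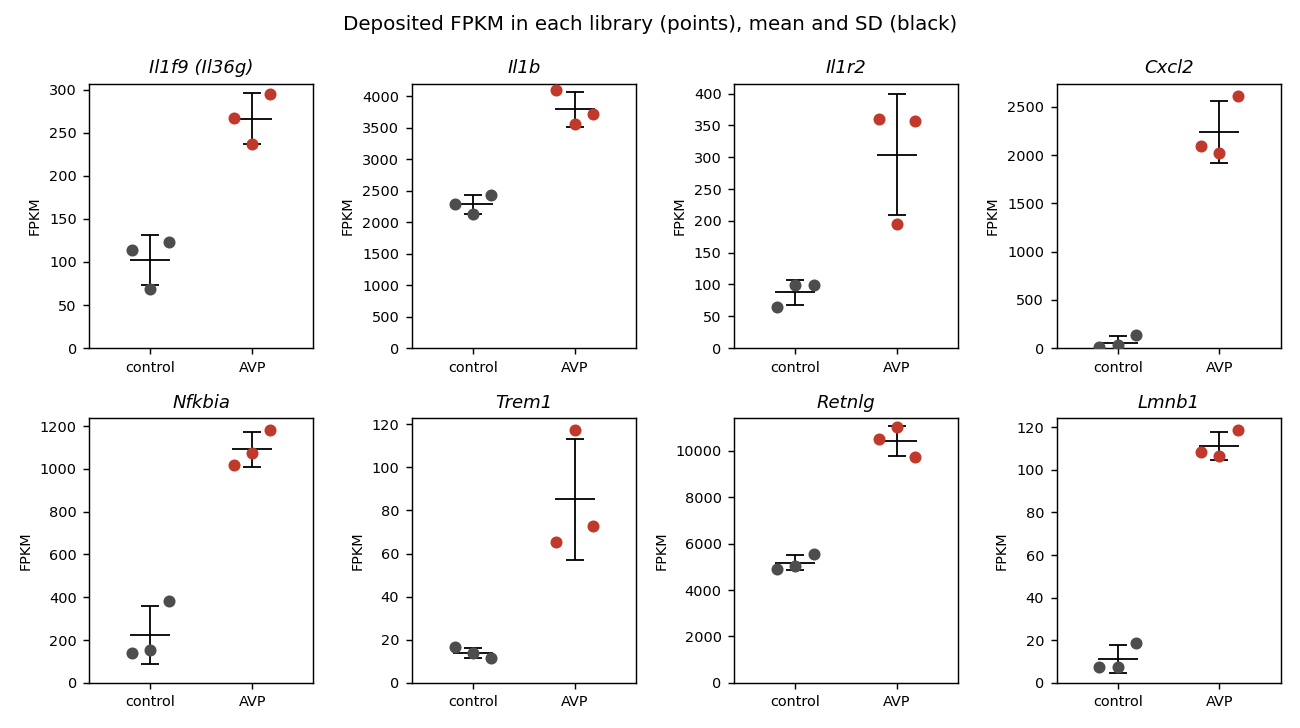
Deposited FPKM (vertical axes, linear, starting at 0) of 8 genes in the 3 control and 3 AVP libraries; points are libraries, the wide black line is the mean and the error bar is 1 SD. Il36g, shown as Il1f9, lies between 68.7 and 123 FPKM in controls and between 236 and 295 FPKM after AVP.

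Among the 15 genes with the smallest p, Cxcl2, Cxcl3, Nfkbia and Ier3 belong to the fixed NF-kB list and were higher after AVP. Cxcl2, a chemokine that attracts neutrophils, was at 57.9 ± 67.7 FPKM in controls and 2243 ± 321 FPKM after AVP (SD, n = 3), a log2 fold change of 6.07 (SE 0.78, adjusted p = 0.0659). Cxcl3, a related chemokine, was listed at 0 in all 3 control libraries and at 27.5, 57.6 and 29.7 FPKM in the AVP libraries. Ccrl2, a receptor that binds chemerin, had a log2 fold change of 4.93 (SE 0.68), and Trem1, a receptor that amplifies inflammatory signalling in myeloid cells, one of 2.58 (SE 0.35). Lmnb1, which encodes lamin B1 of the nuclear envelope, was at 11.3 ± 6.56 FPKM in controls and 111 ± 6.5 FPKM after AVP (SD, n = 3). The transcription factor gene Ets2 had a log2 fold change of 3.08 (SE 0.39), the GTPase-activating protein gene Tagap one of 3.13 (SE 0.43), and Nfkbid, an atypical inhibitor of NF-kB, one of 2.51 (SE 0.32). Retnlg, an abundant transcript of mouse neutrophils, was at 5173 ± 322 FPKM in controls and 10430 ± 664 FPKM after AVP (SD, n = 3). Glipr2 and Selenok had log2 fold changes of 1.85 (SE 0.26) and 1.38 (SE 0.22). Hddc2 was the gene among the 15 with the smallest p that was lower after AVP: it was listed at 0 in all 3 AVP libraries and at 18.6, 9.99 and 15.3 FPKM in the controls.

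These 15 genes did not pass the threshold of 0.05 over all genes, their adjusted p by limma lying between 0.0659 and 0.11. Of 8523 genes tested, 0 were higher and 0 lower at an adjusted p under 0.05, and 400 were higher and 322 lower at an unadjusted p under 0.05, where chance gives 426 in all. Which direction had more genes depended on the scaling (346 higher and 376 lower on the deposited scale, 365 and 370 with haemoglobin, immunoglobulin and mitochondrial genes removed) and on the libraries (312 and 423 without AVP replicate 2, 362 and 408 without AVP replicate 3). At a looser adjusted p under 0.1, 12 were higher and 1, Hddc2, was lower. In 1195 genes (14%) the groups did not overlap, where chance gives 10%. Without control replicate 3, in which Cxcl2 (135 FPKM), Ccrl2 (25.6 FPKM) and Nfkbia (382 FPKM) were highest among the controls, 4 genes were higher and 0 lower: Nfkbia, Ccrl2, Lmnb1 and Cxcl2. With a filter of 10 FPKM in at least 3 libraries, chosen after seeing the data, 11 genes were higher and 0 lower.

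By camera with the preset correlation, the fixed lists of NF-kB targets, cytokines and chemokines (adjusted p = 6.63e-13) and of immediate early and handling stress genes (adjusted p = 1.49e-15) rose after AVP. Each call was lost with an estimated correlation (adjusted p = 0.13 with an estimated correlation for both), and each had an adjusted p of 0.0131 by fry, which tests whether the genes move on balance in the same direction. The estimated setting has 4 residual degrees of freedom, so the loss alone does not show that members vary together. Of the 36 tested members of the NF-kB list, 10 rose and 0 fell, adjusted over the list alone, 26 did not pass, and 0 passed over all genes; the median log2 fold change was 0.90. Besides Cxcl2 and Cxcl3, Nfkbia, which encodes the inhibitor that shuts NF-kB off, rose from 225 ± 136 to 1091 ± 83.1 FPKM (SD, n = 3). Ier3, an early response gene, rose by a log2 fold change of 1.64 (SE 0.22). Of the 26 tested immediate early and handling stress genes, 7 rose and 0 fell, adjusted over the list alone, 19 did not pass, 0 passed over all genes, and all 26 had a fitted fold change above 0 (median 0.89). Among them were Fosb (log2 fold change 3.23, SE 0.51), a subunit of the AP-1 transcription factor, Atf3 (2.33, SE 0.41), a stress-induced transcription factor, Gadd45b (1.603, SE 0.25) and Dusp1 (0.90, SE 0.20), a phosphatase that switches off MAP kinases.

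Of the 21 mature blood neutrophil genes, 6 rose and 1 fell, adjusted over the list alone (0 over all genes): the 4 with the smallest p were Trem1, Retnlg, Il1r2 and Mxd1 (log2 fold change 1.37, SE 0.27), a repressor of the MYC network. The gene that fell, Fpr2, a formyl peptide receptor named after its values were seen, went from 164 ± 23.4 to 76.3 ± 19.7 FPKM (SD, n = 3). The list rose by camera (adjusted p = 0.000109, and adjusted p = 0.34 with an estimated correlation). The calprotectin and stefin list rose (12 tested, median 0.48, adjusted p = 0.000378, and adjusted p = 0.158 with an estimated correlation), although 0 of its members passed and its most abundant genes had log2 fold changes of -0.06 (S100a8) and 0.15 (S100a9). Of 14 genes of immunosuppressive and tumour-associated neutrophils, 1 rose, adjusted over the list alone, which was Trem1, and the list rose (adjusted p = 0.000484, and adjusted p = 0.255 with an estimated correlation). Of 15 secondary and tertiary granule genes, 2 rose, adjusted over the list alone: Lcn2, the iron-scavenging lipocalin 2, from 339 ± 123 to 882 ± 119 FPKM (SD, n = 3), and Adam8, a metalloprotease (log2 fold change 1.29, SE 0.35). The granule list itself did not pass (adjusted p = 0.19). Of 4 tested primary granule genes (Srgn, Lyz2, Ctsc and Cd63) 1 rose, Srgn, the granule proteoglycan serglycin (0.79, SE 0.16), and this list did not pass either (adjusted p = 0.32). Its members Mpo, Elane, Ctsg, Ms4a3 and Bpi were listed at 0 in all 6 libraries, so the list says nothing of them. Mpo, Elane and Ctsg also belong to the extracellular trap and neutrophil progenitor lists. Of 22 chemotaxis and adhesion receptors 1 rose, Ccrl2, and of 27 Toll-like receptor and inflammasome genes 1 rose, Tlr2 (2.38, SE 0.49), a sensor of bacterial lipoproteins; the lists had adjusted p of 0.32 and 0.939.

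By camera with the preset correlation, the fixed lists of glucocorticoid response, cAMP and CREB target, and JAK-STAT3 and G-CSF signalling genes rose (adjusted p = 0.00227, 0.000476 and 0.000677). Each of these calls was lost with an estimated correlation (adjusted p = 0.255 with an estimated correlation for all 3). Of 12 glucocorticoid response genes, 6 rose and 1 fell, adjusted over the list alone (0 over all genes). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose from 141 ± 4.83 to 273 ± 56.5 FPKM (SD, n = 3), Il1r2 and Dusp1 rose, and Sesn1, a p53 and FOXO target, fell by 2.05 on the log2 scale (SE 0.57). Of 14 cAMP and CREB target genes 4 rose, adjusted over the list alone, Fosb, Atf3, Dusp1 and Pde3b, of which 3 are also in the immediate early list; Pde3b, a phosphodiesterase, was at 7.35, 7.67 and 6.95 FPKM after AVP and at 0, 0 and 1.64 FPKM in controls. Of 17 genes of JAK-STAT3 and G-CSF signalling 1 rose and 16 did not pass, adjusted over the list alone. The gene that rose was Osm, the cytokine oncostatin M (2.71, SE 0.56). Osm is also in the NF-kB list, as are Socs3, Bcl3 and Cebpb, so the lists are not separate signals.

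The lists of ribosomal protein, mitochondrially encoded and B cell genes fell by camera with the preset correlation, with 0 single members past the test in any of them. All 3 calls were lost with an estimated correlation (adjusted p = 0.663, 0.554 and 0.45 with an estimated correlation). Of 79 ribosomal protein genes 69 had a fitted fold change below 0 (median -0.30, adjusted p = 5.89e-06), including Rps27 (-0.54, SE 0.25) but not Fau (0.03, SE 0.18), whose sign turned on the deposited scale (-0.05). Of 15 mitochondrially encoded genes 15 lay below 0 (median -0.56, adjusted p = 1.08e-05), including mt-Rnr2 (-0.22, SE 0.25) and the gene of ATP synthase subunit 6, ATP6 (-0.88, SE 0.40). Of 20 B cell genes 16 lay below 0 (median -0.81, adjusted p = 0.0038). AVP replicate 3 stood at the level of the controls for ribosomal protein genes (7.18% of the total FPKM, against 7.29%, 7.78% and 6.39%) and for mitochondrially encoded genes (2.5%, against 2.47%, 2.98% and 2.05%), while AVP replicates 1 and 2 were at 4.25% and 5.29% and at 1.05% and 1.39%. Igkc, the immunoglobulin kappa constant region, was at 4563, 6228 and 3355 FPKM in controls and at 653, 3300 and 2710 FPKM after AVP, while the B cell receptor gene Cd79a was at 415, 464 and 466 FPKM in controls and at 244, 628 and 405 FPKM after AVP. Without AVP replicate 1 the B cell list no longer passed (adjusted p = 0.0961).

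RNA of red cells and of other leukocytes differed between the libraries. Haemoglobin genes took 13.6%, 19% and 17.6% of the total FPKM in the controls and 29.2%, 15.1% and 17% in AVP replicates 1 to 3. The erythroid list rose (10 tested, adjusted p = 0.0489, and adjusted p = 0.663 with an estimated correlation), with Hba-a1 at a log2 fold change of 0.48 (SE 0.33) and Hbb-bs at 0.28 (SE 0.30), and it did not pass without AVP replicate 1 (adjusted p = 0.741). The alpha and beta globin genes have near-identical copies, so the split of fragments between them is uncertain. Mcpt8 and Prss34, proteases of basophils, were at 230 and 28.4 FPKM in AVP replicate 1 and listed at 0 in the other 5 libraries. Other genes of the basophil list were also above 0 in control replicate 2. Cpa3 was at 23 FPKM in AVP replicate 1 and 3.78 FPKM in control replicate 2, and Cyp11a1 at 22.6 and 2.46 FPKM. Il4 was at 11.6 FPKM in AVP replicate 1 and 14 FPKM in control replicate 2, and Fcer1a at 0 and 9.07 FPKM. Trac, the T cell receptor alpha constant region, was at 52.4 FPKM in AVP replicate 3 and listed at 0 in the other 5 libraries, and Cd3d was at 19.8 FPKM there and at 0 to 10.4 FPKM elsewhere. Other genes of AVP replicate 3 were named after their values were seen. Trbc2 was at 33.1 FPKM there and at 0 to 0.94 FPKM elsewhere, and Nkg7 at 44.3 and 0.888 to 1.67 FPKM. Of the monocyte markers, Ms4a4c was at 4.03 FPKM there and at 105 to 174 FPKM elsewhere, and Ctss at 85.4 and 230 to 488 FPKM. Not all markers followed, and Treml4 was at 18.6 FPKM there and at 1.89 to 19.1 FPKM elsewhere. The basophil and T cell lists had fewer than 3 members past the filter and were not tested.

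**Figure D2:**
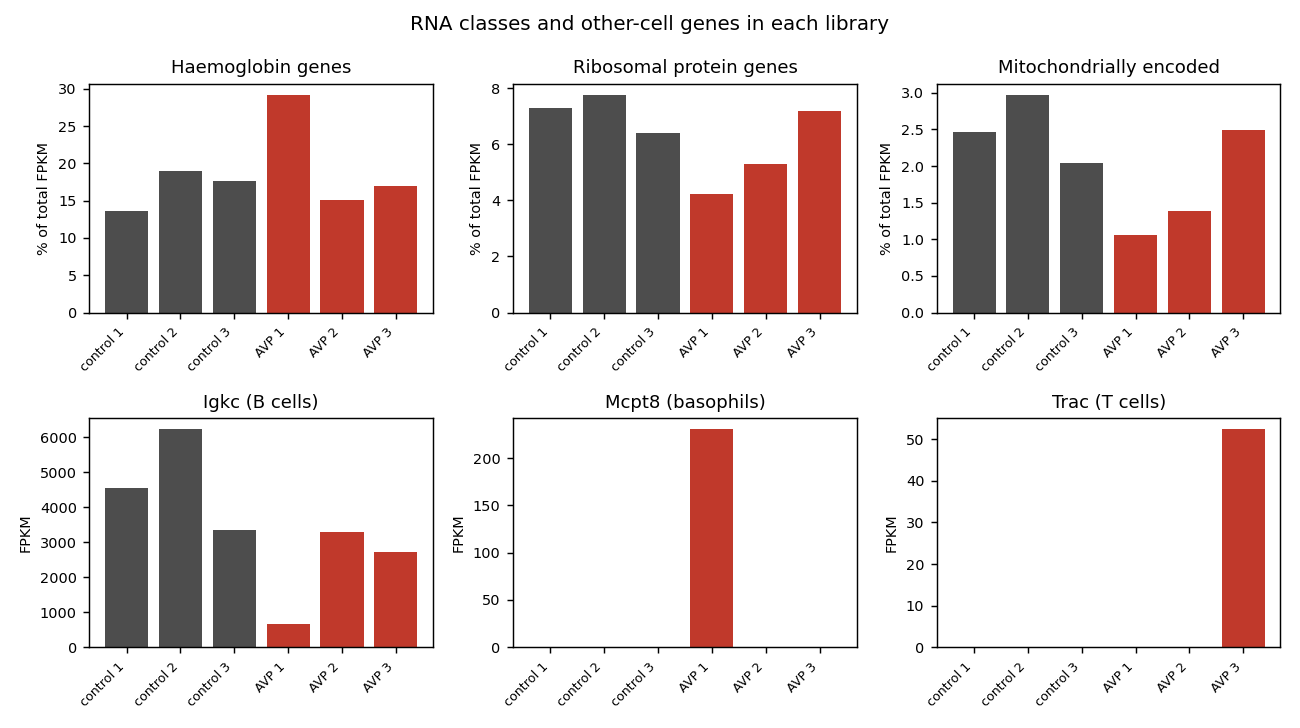
Shares of the total FPKM (upper row, percent) taken by haemoglobin, ribosomal protein and mitochondrially encoded genes, and FPKM (lower row) of Igkc, Mcpt8 and Trac, as bars for each of the 3 control (grey) and 3 AVP (red) libraries. Haemoglobin is highest in AVP replicate 1 (29.2%), Mcpt8 is above 0 in AVP replicate 1 alone and Trac in AVP replicate 3 alone.

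The remaining lists did not pass. The 49 type I interferon response genes had a median log2 fold change of 0.02 and an adjusted p of 0.963, with 24 below 0. The 42 nuclear genes of oxidative phosphorylation had a median of 0.03 (adjusted p = 0.99), the 18 glycolysis genes one of 0.18 (adjusted p = 0.178), and the 17 hypoxia and HIF1 targets one of 0.25 (adjusted p = 0.701). The 13 genes of the NADPH oxidase and oxidative burst (median 0.23), the 4 of extracellular trap formation (0.13), the 9 of aged neutrophils (-0.30), the 9 of the cell cycle (0.13) and the 23 of apoptosis and survival (-0.12) had adjusted p between 0.412 and 0.963. MHC class I genes (15 tested, median 0.25) and MHC class II genes (12 tested, median -0.43) had adjusted p of 0.254 and 0.164. With each library left out in turn, the adjusted p by camera ranged from 0.0138 to 0.835 for MHC class II genes. For glycolysis genes it ranged from 0.0226 to 0.741, so both calls depended on the libraries used. Among other cell types, markers of monocytes (18 tested, median -0.17), dendritic cells (4, -0.81), eosinophils (3, -0.24), platelets (7, -0.88), NK cells (3, 0.09) and neutrophil progenitors (5, 0.09) had adjusted p between 0.452 and 0.963. The median and the test differed in sign for apoptosis, oxidative phosphorylation, eosinophil and neutrophil progenitor genes. Of 3 tested sex-linked genes, Eif2s3y fell by 1.47 on the log2 scale (SE 0.42), adjusted over the list alone, and the list did not pass (adjusted p = 0.347). The groups overlapped for the others, Ddx3y and Uty. Ddx3y was at 22.6, 17.5 and 6.06 FPKM in controls and at 9.84, 12.7 and 33.4 FPKM after AVP. Of the Avp peptide and its receptors, Avpr2 was at 6.19, 5.34 and 5.21 FPKM in controls and at 2.46, 3.69 and 5.12 FPKM after AVP, a log2 fold change of -0.44 (SE 0.56), and Lnpep had one of -0.53 (SE 0.82). This list had 2 members past the filter and was not tested, Avp and Avpr1a were listed at 0 in all 6 libraries, and Avpr1b was at 0.0286 FPKM in AVP replicate 3 and listed at 0 in the other 5.

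**Figure D3:**
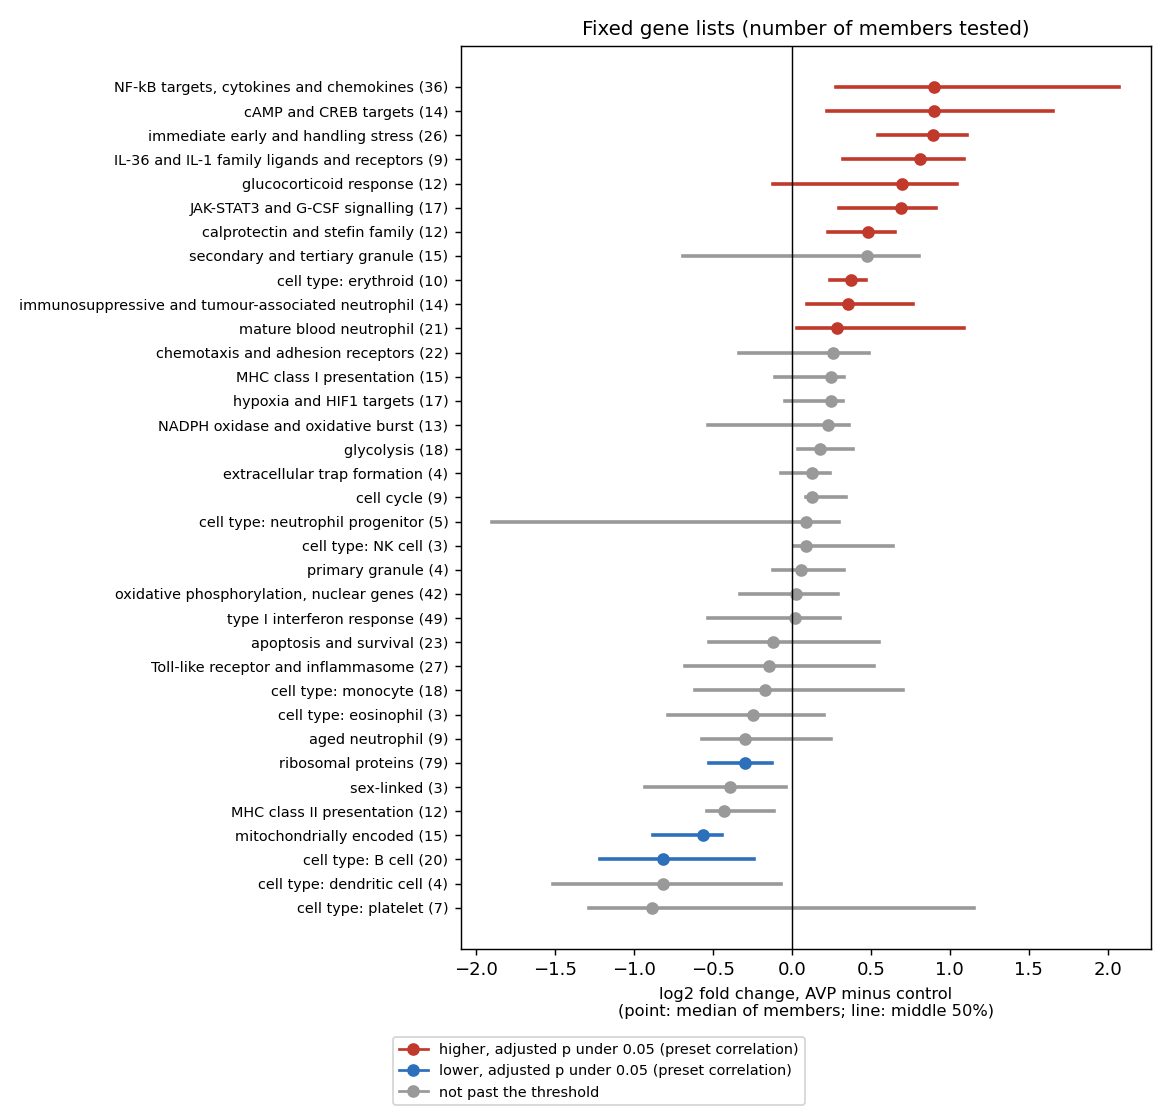
Median log2 fold change (AVP minus control, horizontal axis) of the tested members of each of 35 fixed gene lists (point), with the middle 50% of members (line) and the number of members tested in brackets. Red lists are higher and blue lists lower at an adjusted p under 0.05 by camera with the preset correlation (10 and 3 lists), and 0 lists pass with an estimated correlation, a setting with 4 residual degrees of freedom.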

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

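The values here lie outside the tested genes, in cell-type marker genes that the filter removed. The search for them was chosen after seeing the data. It took markers at 0 in all 3 controls that reached 20 FPKM in an AVP library, so it could not flag a control library. Mcpt8, a basophil protease, was at 230 FPKM in AVP replicate 1. Ms4a2, the beta chain of the IgE receptor of basophils and mast cells, was at 21.1 FPKM and Prss34, another basophil protease, at 28.4 FPKM in the same library. Trac, the constant region of the T cell receptor alpha chain, was at 52.4 FPKM in AVP replicate 3.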

How the results depend on the processing

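Pseudocounts of 0.1 and 5, the 10 FPKM filter and the fit with no intensity trend were chosen after seeing the data. Genes higher after AVP at an adjusted p under 0.05 went from 0 to 3 with a pseudocount of 5, 11 with the 10 FPKM filter (3675 genes tested), 1 with no intensity trend, and 0 to 4 when each library was left out; genes lower stayed at 0 throughout. A pseudocount of 0.1, other scalings, no filter, robust moderation and removal of haemoglobin, immunoglobulin and mitochondrial genes gave 0 and 0. The Il36g log2 fold change stayed between 1.25 and 1.65 in 16 alternatives, with adjusted p between 0.11 and 0.668. Lists past the threshold went from 13 to 0 with an estimated correlation and 2 by fry, were 11 to 14 when each library was left out, and were 0 without AVP replicate 1 with an estimated correlation, a setting also chosen after seeing the data. The replicate block gave 0 genes higher, 0 lower and 12 lists; correlations of same-numbered samples (0.02, -0.01 and -0.04) gave no sign of pairing, and not every sample correlated best with its own number. Without scaling the median over all genes was -0.11, against -0.04. Over 43 other named genes, 646 of 673 alternative values kept their direction and side of the threshold, 19 newly passed and 8 turned sign. Fau turned to -0.0509 on the deposited scale and to -0.0464 with haemoglobin, immunoglobulin and mitochondrial genes removed; leaving out each library gave ranges of -0.0826 to 0.17 for Fau, -0.444 to 0.0181 for mt-Rnr2, -0.45 to 1.89 for Cd3d, -0.38 to 0.19 for Cd79a and -0.0565 to 0.51 for Hbb-bs. The cause was not tested, except that the 10 FPKM filter tests fewer genes and leave-outs use fewer libraries. The planned count-based fits, random thinning and a CPM filter were not run, since the values are not counts. Low genes were often listed at 0, for a reason that was not tested. Of genes with a mean under 5 FPKM, 47.4% were listed at 0 in at least 1 library, and of those at 5 to 10 FPKM, 27.3%. The median residual SD on the log2 scale was 0.87 under 5 FPKM, 0.96 at 5 to 10 FPKM and 0.29 at 500 FPKM or more.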

Other observations

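Genes outside the fixed lists, chosen after their values were seen, also differed in level between the groups, and 0 of them passed over all genes. Acod1, which makes the immunometabolite itaconate, was at 64, 50.1 and 97.3 FPKM after AVP and at 6.41, 4.03 and 15.6 FPKM in controls (log2 fold change 3.09, SE 0.53, adjusted p = 0.12 by limma). Hcar2, the receptor for niacin and beta-hydroxybutyrate, had a log2 fold change of 2.76 (SE 0.53), Trib1, a pseudokinase that controls degradation of C/EBP factors, one of 2.85 (SE 0.46), and Slc16a3, the lactate exporter, one of 2.28 (SE 0.54). Gadd45a (1.32, SE 0.22), Litaf (1.159, SE 0.24) and Fth1, the ferritin heavy chain (0.62, SE 0.15), were higher in all 3 AVP libraries than in all 3 controls. Lower in all 3 AVP libraries than in all 3 controls were Cybc1, the chaperone of the phagocyte NADPH oxidase (-2.30, SE 0.48), Ndufa5, a complex I subunit (-1.87, SE 0.40), Capg, an actin-capping protein (-1.80, SE 0.46), and Iglc2, an immunoglobulin lambda constant region (-1.72, SE 0.38).

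The explanations below and what each predicts were chosen after the results were seen, while the list tests with the preset and an estimated correlation, by fry and without each library were planned. NF-kB target and immediate early genes were higher as lists in the AVP libraries, each with an adjusted p = 0.13 with an estimated correlation, and 26 of 36 and 19 of 26 members did not pass over the list alone. The tables argue against more monocytes at unchanged expression per cell, since the 18 monocyte markers did not rise on balance. Their median log2 change was -0.17 (SD 0.93), with 8 above 0 and 10 below. The 10 passing NF-kB genes had a median of 2.78, which is raised by picking genes that passed. All 36 tested NF-kB genes had a median of 0.90. Stress during handling and sorting stays open: the 5 tested heat shock genes had a median log2 change of 0.96 (0.64 to 1.44), and 1 of them, Hspa8, passed when adjusted over the list alone. A response to AVP in the animal is the biological explanation and stays open too. The 10 splits of the 6 libraries are too few for a share under 0.05: the real split gave a -log10 p of 13.4 for the NF-kB list (1 of 10 splits as large) against a highest other of 4.01.

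B cell, ribosomal protein and mitochondrially encoded genes were lower as lists with the preset correlation, and each call was lost with an estimated correlation (adjusted p = 0.45, 0.663 and 0.554) and by fry (0.34, 0.549 and 0.505). Without AVP replicate 1 the medians moved from -0.81 to -0.36, from -0.30 to -0.16 and from -0.56 to -0.42, with adjusted p of 0.0961, 0.0181 and 0.0075 at the preset correlation and 0.418, 0.922 and 0.922 with an estimated correlation, a fit chosen after the results were seen. AVP replicate 1 may therefore carry the B cell call. For the other lists these adjusted p cannot tell AVP replicate 1 from a shift in more libraries. The preset and estimated settings disagree, and the estimated setting has 3 residual degrees of freedom there. As shares of the total FPKM, AVP replicate 2 also lay below every control, and AVP replicate 3 did not. AVP replicate 2 was at 5.29% against 6.39% to 7.78% for ribosomal protein genes, and at 1.39% against 2.05% to 2.98% for mitochondrially encoded genes. A smaller share of B cells at unchanged expression per cell stays open. If genes vary independently, the B cell changes differed more than their errors allow (Cochran's Q 56.4 with 19 degrees of freedom over 20 genes). That result leans on Ighd, at 1.25 (SE 0.32) against a weighted mean of -0.43, which went the other way. Because it leans on 1 gene and the members may vary together, Q cannot decide. A difference in RNA quality and a response to AVP stay open and were not tested.

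In 7 genes every library of one group was listed at 0 and every library of the other stood at 5 FPKM or more: Cxcl3 at 0 in controls, and Hddc2, Guca1a, Tprkb, Slc25a4, Gm1647 and Tmem184c at 0 after AVP. A count of 7 is no more than other splits of the libraries gave (5 to 13), and 8 of the 10 splits gave as many. The count therefore does not tie these genes to AVP. It cannot show why a gene was listed at 0, so dropout of low-abundance genes stays open. Levels in the other group ran from 5.09 FPKM (Gm1647, control replicate 3) to 57.6 FPKM (Cxcl3, AVP replicate 2), so not all were low.

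The real split gave 0 genes past the threshold (highest other 3), so a count of splits says nothing there. For genes at an unadjusted p under 0.05, 1 of 10 splits gave as many (722, highest other 608), and for lists past the threshold 1 of 10 (13, highest other 10). Such a design cannot give a share under 0.05.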
